A study of Mus musculus with 60 samples.

How the data were processed

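RNA from 60 mouse livers was hybridised to Agilent 2-colour whole-genome arrays (design 028005), with the liver RNA in Cy5 and a universal mouse reference RNA in Cy3, per the labels. Scanner output files of 60 arrays and a table of the authors' normalized values for the same arrays were used. Median and background intensity values in both channels came from Agilent Feature Extraction 11.0.1.1 with its grid annotated to mm9, per the file headers. The processed signals in those files are intensity values that the scanner software had background-subtracted and dye-normalized, per the file headers. The flags for spots well above background, saturated or outlying are of another kind, 0 or 1 per spot, per the file headers. The deposited series matrix holds log2 values, 1 column per array. Set against the scanner signals of the same array, its columns rose with a slope of 0.986 to 0.999 and a correlation of 0.995 to 0.998, so their scale and their direction, Cy5 over Cy3, could be read from the data, and all columns matched a sample. Column medians lay between −0.0261 and −0.00413. How the authors normalized these values is not given in the sources used here. Gene positions were not used.

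The files hold median and not mean pixel signals, so medians replaced the means that had been planned, and the planned comparison of mean with median signals could not be run. Signals were background-corrected with normexp (offset 50) on the local background, and each array was normalized by loess with 3671 control spots and outlier spots (198 to 345 per array) at weight 0. No array had saturated Cy5 spots. Spots of 1 probe were averaged, and 59305 spots that were not controls gave 55681 probes. Probes were named by RefSeq accession through a table of gene names: 27235 (48.9%) received a symbol and 28446 stayed unnamed. A probe was kept if it was well above background in Cy5 on at least 5 of the 60 arrays, which left 30197. For the 3474 genes with more than 1 probe left, the probe with the highest mean Cy5 signal stood for the gene, and the text says where other probes went the other way. This gave 26084 features, 14402 named genes and 11682 unnamed transcripts, with 180 missing values. Median Cy5 signals were 78.5 to 108 and backgrounds 65 to 74 per array, and 47.7% to 61.4% of the spots that were not controls were well above background in Cy3. Dim probes limit what these arrays can show.

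Each feature's log2 ratio was fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3 as 12 group means over 60 arrays, with 48 residual degrees of freedom. Contrasts were each exposed group against its own vehicle group, the difference of these effects between particles and between days, and the difference between vehicle groups of 1 day. All tests were two-sided, and p values were adjusted by Benjamini and Hochberg within each contrast. Features with an adjusted p under 0.05 passed. Differences are exposed minus vehicle, NM-401 minus NRCWE-26, later day minus day 1, and NM-401 vehicle minus NRCWE-26 vehicle. A gene that was not well above background on any array of a group has only a bound there. Its fold is given as at least the mean of the brighter group over the dimmer group's floor, taken from Cy5 after loess and Aquantile as, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Since the dyes were not swapped, such a bound is open to dye bias, and it holds on this scale only: quantile-normalized Cy5 changed by −3.56 for Scd3, 3.18 for Prtn3 and −1.55 for Cyp2c55, which are smaller than their bounds. For Scd3, Cela1 and Cyp2c55 the bound equals the fold of the probe's own signals. The reference channel was looked at in genes whose Cy5 signal moved by 2 or more: Cy3 moved by a median 0.0493, 0.0666 and 0.0170 of the Cy5 change after NRCWE-26 and 0.0850, 0.0443 and 0.00434 after NM-401 on days 1, 3 and 28. These medians do not describe the abundant acute phase genes. Of 321 changes of named genes 27 came with a Cy3 change of 1 or more, 22 in the direction of Cy5 (among them Saa1, Saa2, Lcn2, Orm2, Lbp, Apcs, Apoa4 and Cyp1a2) and 5 against it (Mt1, Mt2 and C3). The cause was not tested.

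Gene lists numbered 31, all fixed before the data were examined, as were the model, the threshold and the rule for naming genes. They cover positive and negative acute phase proteins, cholesterol synthesis and uptake, cholesterol efflux and lipoproteins, bile acids, fatty acid synthesis, PPARα targets, gluconeogenesis, xenobiotic metabolism, NRF2 targets, interferon response, cytokines, the unfolded protein response, heat shock, cell cycle, the circadian clock, iron handling, complement and coagulation, and matrix genes. The other lists hold markers of neutrophils, Kupffer cells, T and NK cells, B cells, endothelium, stellate cells, bile duct cells, red cells, adipocytes, hepatocytes, lung epithelium and pancreatic acinar cells. Camera of limma tested each list against all other genes with a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. Fry tests whether a list's genes move on balance 1 way and does not compare them with other genes. Genes were named by a rule: in each exposed group the 5 largest rises and 5 largest falls among passing genes with every exposed array on the same side of the vehicle mean, leaving out predicted genes. Added were up to 3 members with the smallest adjusted p of each list that was called or had at least 3 members passing, and a panel of 12 acute phase and cholesterol genes. Other contrasts name the 3 largest in each direction and panel genes that passed. From these the text takes examples.

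Arrays lay on 8 slides and were scanned on 5 days, and each slide held at most 1 array of a group, so slide entered as a fixed or random block and list means were also taken within each slide. A test of single genes within a slide could not be made with 1 array per group. Arrays of a group correlated with a median r of 0.980 (0.952 to 0.989) and arrays of different groups with 0.962 (0.917 to 0.989). The first principal component held 25.8% of the variance, of which groups explained 94.9%, and the fifth held 5.98%, of which slides explained 78.1%. Other alternatives were no background correction, the scanner's processed signals, Aquantile, the Cy5 channel alone, the series matrix, no or a stricter filter (30 arrays), scan day, only the arrays compared, array weights, another variance prior, mean or single probes, pooled vehicle groups, stricter thresholds (0.01; 1.5-fold) and leaving out each array. Chosen after seeing the data were the first components of 16 clock genes as covariates (75.0% and 15.8% of their variance), leaving out 9 arrays whose mean of pancreatic markers lay above 2, and the vehicle group of the other particle as control. The clock covariates differ between groups, so they also take away part of any real effect on clock genes and what moves with them. Collection time of day is not given in the sources used here. The scripts were tested on simulated data for day 1 after NRCWE-26 with 25926 features of which 200 were changed: 72.0% of changes of 0.5 were found, 98.0% of 1 and 100% of 2 or 3 (log2), with 8 false calls, and 0 genes were called in a simulated day 28 contrast with no change. The simulated noise was drawn independently for each gene and array, without slide, clock or pancreatic structure. Its counts therefore test the scripts and not the error rate in the real arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the figures. Some genes that the naming rule picks are not reported here. They stay in the counts of genes and list members, but not in the test for outlying arrays.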

Results

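Liver gene expression was measured in female C57BL/6 mice after a single intratracheal instillation of multi-walled carbon nanotubes. NRCWE-26 is a short nanotube, which the sample labels spell NCRWE-026, and NM-401 is a long one. Mice received 162 µg of either particle or the vehicle, water with serum, and their livers were taken 1, 3 or 28 days later. Each particle had its own vehicle group on each day, which gave 12 groups of 5 arrays, 60 in all. The protocol text speaks of groups of 6 mice and the design text of 72 samples, a pulmonary response and 3 doses, whereas the extraction protocol names liver tissue and the arrays analysed here hold 162 µg and vehicle. Each array set liver RNA in Cy5 against a universal mouse reference RNA in Cy3. Between 38.1% and 58.3% of the spots that were not controls were well above background in Cy5 (median 44.4%), and 26084 genes or unnamed transcripts were tested. The number of arrays limits the precision of every value. The series title names cholesterol homeostasis and the acute phase response, so these genes come first in each comparison. Values are log2 differences between exposed and vehicle arrays with the standard error of the limma fit, each from 5 exposed and 5 vehicle arrays unless another number is given.

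**Figure D1:**
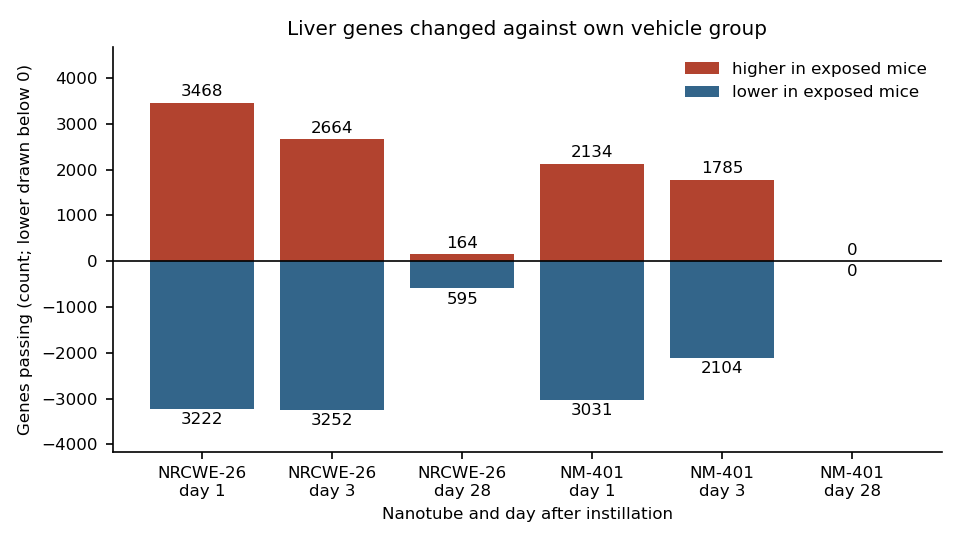
Bars give the number of genes or unnamed transcripts with an adjusted p under 0.05, higher (upwards) and lower (downwards), for each particle and day against its own vehicle group. The numbers were 6690, 5916 and 759 after NRCWE-26 and 5165, 3889 and 0 after NM-401 on days 1, 3 and 28.

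The first comparison asked what NRCWE-26 did to the liver 1 day after instillation. Acute phase proteins, which the liver secretes in inflammation, were higher: 14 of the 33 listed genes rose, 0 fell and 19 did not pass. Lcn2, an iron-scavenging protein, rose by 2.36 ± 0.43 (5.15-fold), the orosomucoid gene Orm3 by 2.22 ± 0.36, and Stat3, the transcription factor of interleukin 6 signalling, by 0.81 ± 0.16, although the Stat3 call ended with clock components as covariates. The serum amyloid genes Saa1 and Saa2 rose by 1.23 ± 0.43 and 1.46 ± 0.49 (adjusted p 0.0258 and 0.0206), with 5 of 5 exposed arrays above the vehicle mean. The groups overlapped, as vehicle replicate 3 lay at 6.62 and 9.18 and exposed replicate 1 at 5.30 and 7.76. These Saa calls ended with the clock covariates, without the arrays that held pancreatic markers, with only the arrays compared, and without any of several single arrays. The reference channel, Cy3, rose as well for Saa1, Saa2 and Lcn2, by 1.75, 1.64 and 1.56, beside Cy5 changes of 3.02, 3.08 and 3.92. Saa3 (0.37 ± 0.28) and Orm2 (0.37 ± 0.23) did not pass. The list moved as a whole by 0.60 (camera adjusted p = 5.59e-04), but adjusted p = 0.812 with an estimated correlation and the call was lost with the scanner's processed signals. With slide as a block the adjusted p was 4.16e-04, within slides the mean ranged from 0.37 to 0.96, and 15 genes passed when adjusted over the list alone.

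Genes of cholesterol synthesis and uptake, the targets of the transcription factor SREBP2, moved the other way on day 1: 21 of 25 fell and 0 rose. Hmgcs1, an early enzyme of the pathway, was 4.03-fold lower (−2.01 ± 0.39). Sc5d, a late enzyme of the pathway, was 5.01-fold lower (−2.32 ± 0.18), and the mevalonate pathway kinase gene Pmvk was 3.03-fold lower (−1.60 ± 0.20). The squalene epoxidase gene Sqle changed by −1.04 ± 0.36, a call that ended with the clock covariates. Srebf2, which encodes SREBP2 itself, stood at 0.14 ± 0.21 and did not pass. The list mean was −1.06 (camera adjusted p = 4.83e-10, adjusted p = 0.660 with an estimated correlation, 5.97e-08 with slide as a block), within slides from −1.88 to −0.31, and 22 genes passed adjusted over the list alone. Genes of cholesterol efflux and lipoproteins went both ways, with 4 of 21 higher and 7 lower. The sterol exporter Abca1 rose by 0.54 ± 0.13 and Mylip, a ubiquitin ligase, by 1.05 ± 0.10, while the exporter Abcg8 changed by −1.92 ± 0.23. Among bile acid genes 3 of 19 rose and 2 fell. The bile acid receptor gene Nr1h4 rose (0.70 ± 0.12), its target Nr0b2 was lower (−2.15 ± 0.42), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at −0.02 ± 0.60 and did not pass.

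The largest single rises on day 1 after NRCWE-26 were in Sult1e1, an estrogen sulfotransferase, at 43.1-fold (5.43 ± 0.55), and in the lipid droplet genes Cidec (22.2-fold) and Plin4 (18.4-fold). Eif4ebp3, a repressor of translation, was 14.8-fold and Bmper, which binds bone morphogenetic proteins, 8.84-fold higher. The largest falls were in the ubiquitin ligase gene Rnf186 (16.3-fold), the water channel Aqp8 (11.2-fold), cyclin D1 (Ccnd1, 8.66-fold), the glycogen-targeting phosphatase subunit Ppp1r3g (7.56-fold) and the U1 spliceosomal RNA gene Rnu1b6 (6.73-fold). Against the other particle's vehicle arrays the Ppp1r3g call ended and Rnu1b6 changed by only −0.75. Fatty acid synthesis genes were lower, with 8 of 19 down and 1 up: Srebf1, their transcriptional activator, was 5.13-fold lower (−2.36 ± 0.20) and Acss2, which makes acetyl-CoA, 4.53-fold lower (−2.18 ± 0.26). Of 26 PPARα targets and fatty acid oxidation genes 8 rose and 2 fell, among them Acadl (0.79 ± 0.11) and Cpt1a (0.77 ± 0.14), which carry out and gate mitochondrial oxidation. Genes of the unfolded protein response rose in 11 of 19 cases and fell in 2, with Hspa5 at 1.78 ± 0.23, Creld2 at 2.17 ± 0.31 and Manf at 1.82 ± 0.26. Interferon response genes fell in 16 of 20 cases, with Isg15 at −1.23 ± 0.13, Ifit3 at −1.16 ± 0.18 and Igtp at −0.90 ± 0.17. Of 15 NRF2 targets 6 fell, among them Gclc of glutathione synthesis (−1.17 ± 0.16), and 1 rose, the heme oxygenase Hmox1 (1.02 ± 0.21). Il1r1, the interleukin 1 receptor, rose by 2.45 ± 0.29 within a cytokine list in which 3 of 15 rose and 2 fell, with a mean of 0.12 and a median of −0.17 that differ in sign.

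In total 6690 genes passed at day 1 after NRCWE-26 (3468 higher, 3222 lower), of which 2113 differed by at least 1.5-fold. Camera called 9 of 31 lists, 4 higher and 5 lower. These included fatty acid synthesis (mean −0.60, adjusted p = 9.40e-04, 0.740 with an estimated correlation, within slides −0.95 to 0.11) and PPARα targets (0.46, 0.00756, 0.740 with an estimated correlation, within slides 0.11 to 0.77). They also included the unfolded protein response (0.56, 6.10e-04, 0.660 with an estimated correlation, within slides 0.28 to 1.13) and interferon genes (−0.64, 4.60e-08, 0.660 with an estimated correlation, within slides −0.77 to −0.41). NRF2 targets moved by −0.32 (adjusted p 0.0445, 0.740 with an estimated correlation, within slides −0.54 to −0.03). Of 23 cell cycle genes 2 rose and 4 fell, among them Rrm2 at 1.46 ± 0.25 and the thymidine kinase Tk1 at −1.26 ± 0.11. Their mean was −0.22 (adjusted p 0.0445, 0.958 with an estimated correlation, 0.0601 with slide as a block, within slides −0.48 to 0.05). Markers of lung epithelium moved by 0.60, with the club cell gene Scgb1a1 at 0.63 ± 0.06 the only 1 of 4 to pass (0.0445, 0.660 with an estimated correlation, 0.0702 with slide as a block, within slides 0.41 to 0.82). Scgb1a1 is thus a measured change in a gene of another tissue. No list was called with an estimated correlation, and 11 were called by fry.

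By day 3 after NRCWE-26 more of the acute phase list had moved. Of 33 genes 23 rose and 0 fell: Lcn2 was 14.6-fold higher (3.87 ± 0.43), Saa1 5.64-fold (2.50 ± 0.43) and Saa2 7.32-fold (2.87 ± 0.49). In the Cy5 channel alone these changes were 6.46, 6.09 and 6.19, and the reference channel rose by 2.31, 3.22 and 3.15, so the folds depend on how the channels are read. Steap4, a metalloreductase, rose by 3.09 ± 0.33, the pentraxin Apcs by 2.61 ± 0.28, Lbp, which binds bacterial lipopolysaccharide, by 1.16 ± 0.13, Saa3 by 1.09 ± 0.28 and Orm2 by 0.67 ± 0.23. The call of Apcs was lost with the scanner's processed signals, that of Saa3 with the clock covariates, and that of Orm2 under several settings. The chemokine Cxcl1, which attracts neutrophils, was 20.1-fold higher (4.33 ± 0.50), and 7 of 15 cytokine genes rose and 0 fell, with Il1r1 at 3.26 ± 0.29 and the adhesion molecule Icam1 at 1.23 ± 0.14. Neutrophil markers rose in 4 of 7 cases, with the calprotectin genes S100a8 at 3.46 ± 0.43 and S100a9 at 3.57 ± 0.52 (11.8-fold) and Retnlg at 1.85 ± 0.18. The list of negative acute phase proteins, such as albumin, was not called (mean 0.04, adjusted p = 0.927), but with the Cy5 channel alone it was called as lower (−0.45, 3.13e-04). The metal-binding genes Mt2 (12.2-fold) and Mt1 (2.41 ± 0.37) and the zinc importer Slc39a14 (1.75 ± 0.21) rose, in a list of iron and metal handling with 5 of 14 up and 3 down. For Mt2 and Mt1 Cy5 rose by 2.22 and 1.03 and the reference channel fell by 1.47 and 1.48, so part of these 2 rises came from the reference.

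The gene with the largest fall on day 3 after NRCWE-26 was Scd1, which desaturates fatty acids, at 46.5-fold lower (95% interval 32.6 to 66.3, −5.54 ± 0.26). Of 19 fatty acid synthesis genes 17 fell and 0 rose, with Fasn at −2.80 ± 0.28 and Me1, which supplies NADPH, at −1.96 ± 0.21. Cyp7a1 was 18.1-fold lower (−4.17 ± 0.60) and 7 of 19 bile acid genes fell while 2 rose, with Hsd3b7 at −1.24 ± 0.13 and Cyp27a1 at −1.24 ± 0.18, although Cyp27a1 was not called with the scanner's processed signals. Cholesterol synthesis genes fell in 14 of 25 cases and rose in 1: Sc5d changed by −1.88 ± 0.18 and Hmgcs1 by −1.34 ± 0.39, and Srebf2 rose by 0.57 ± 0.21. The calls of Hmgcs1 and Srebf2 ended with the clock covariates. For Hmgcs1, NRCWE-26 day 3 replicate 1 lay at 0.337 and the other exposed arrays at 2.26 to 2.52. For the mean of the cholesterol synthesis list they lay at 1.06 and at 1.92 to 2.06. The same array held high pancreatic markers (5.37). Sqle stood at −0.22 ± 0.36 and did not pass, and turned to 0.21 without NRCWE-26 day 3 replicate 1. Abca1 rose by 0.69 ± 0.13, the lipoprotein receptor Lrp1 by 0.82 ± 0.10 and Lcat, which esterifies plasma cholesterol, by 0.81 ± 0.14, in an efflux list with 5 of 21 up and 8 down. Apoa4 rose by 1.67 ± 0.24 and Cyp1a2, a drug-metabolizing enzyme, changed by −1.66 ± 0.19, but with the scanner's processed signals they turned to −0.50 and 0.23. Among 26 PPARα targets 9 rose and 2 fell, with the hormone Fgf21 at 2.40 ± 0.37 and the peroxisomal gene Acaa1b at −0.93 ± 0.12.

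Also at day 3 after NRCWE-26, interferon genes fell in 15 of 20 cases and rose in 0, with Cxcl9 at −2.31 ± 0.30, Ifit3 at −1.55 ± 0.18 and the guanylate-binding protein Gbp3 at −1.58 ± 0.19. Of 15 NRF2 targets 6 fell and 3 rose, the falls including the glutathione transferases Gstm3 (−1.97 ± 0.18), Gstm1 (−1.45 ± 0.14) and Gsta2 (−2.50 ± 0.37). Unfolded protein response genes rose in 14 of 19 cases and fell in 2, with Calr at 1.01 ± 0.11 and Sdf2l1 at 1.96 ± 0.23. Cell cycle genes fell in 7 of 23 cases and rose in 1, with Ccnd1 7.37-fold lower and the cell cycle inhibitor Cdkn1a at 2.28 ± 0.43, which 1 of its 2 probes showed and whose call ended with the clock covariates. Other large changes were in Sult1e1 (23.3-fold higher), the magnesium transporter Slc41a2 (19.5-fold higher), the G-protein regulator Rgs16 (25.5-fold lower), the uridine phosphorylase Upp2 (18.7-fold lower) and the carboxylesterase Ces2b (15.6-fold lower). Of 23 complement and coagulation genes 4 rose and 0 fell. The ratio of C3 among them rose by 1.19 ± 0.24, but its Cy5 signal by only 0.14, while the reference channel changed by −1.23. Col3a1, a fibrillar collagen, changed by −1.49 ± 0.24 with 2 other matrix genes among 12.

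For day 3 after NRCWE-26, 5916 genes passed (2664 higher, 3252 lower, 2053 by at least 1.5-fold), 3249 with the clock covariates, and camera called 11 of 31 lists (5 higher, 6 lower). Fatty acid synthesis moved by −1.67 (adjusted p = 5.67e-22, 0.00669 with an estimated correlation, within slides −1.87 to −1.57) and was the 1 list called with an estimated correlation. The acute phase list moved by 1.31 (1.00e-18, adjusted p = 0.0938 with an estimated correlation, within slides 0.74 to 1.90, 26 genes adjusted over the list alone). Cholesterol synthesis moved by −0.72 (2.38e-06, adjusted p = 0.493 with an estimated correlation, within slides −1.24 to −0.55). Interferon moved by −0.79 (2.53e-10, adjusted p = 0.149 with an estimated correlation, within slides −1.01 to −0.39). The unfolded protein response moved by 0.72 (1.54e-09, adjusted p = 0.0891 with an estimated correlation, within slides 0.51 to 0.96). Cytokines moved by 0.72 (1.98e-04, adjusted p = 0.175 with an estimated correlation, within slides 0.66 to 0.90, ended by the clock covariates). Neutrophil markers moved by 1.32 (2.35e-04, adjusted p = 0.175 with an estimated correlation, within slides 1.13 to 1.64). NRF2 targets moved by −0.54 (0.00292, adjusted p = 0.297 with an estimated correlation, within slides −0.76 to −0.35). Bile acid genes moved by −0.73 (0.0102, adjusted p = 0.496 with an estimated correlation, within slides −1.03 to −0.42, ended by the clock covariates and by the scanner's processed signals). PPARα targets moved by 0.33 (0.0182, adjusted p = 0.564 with an estimated correlation, 0.0576 with slide as a block, within slides 0.19 to 0.28). Cell cycle genes moved by −0.29 (0.00620, adjusted p = 0.564 with an estimated correlation, within slides −0.49 to −0.09). Within-slide ranges at this day cover the 4 slides that held both groups.

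**Figure D2:**
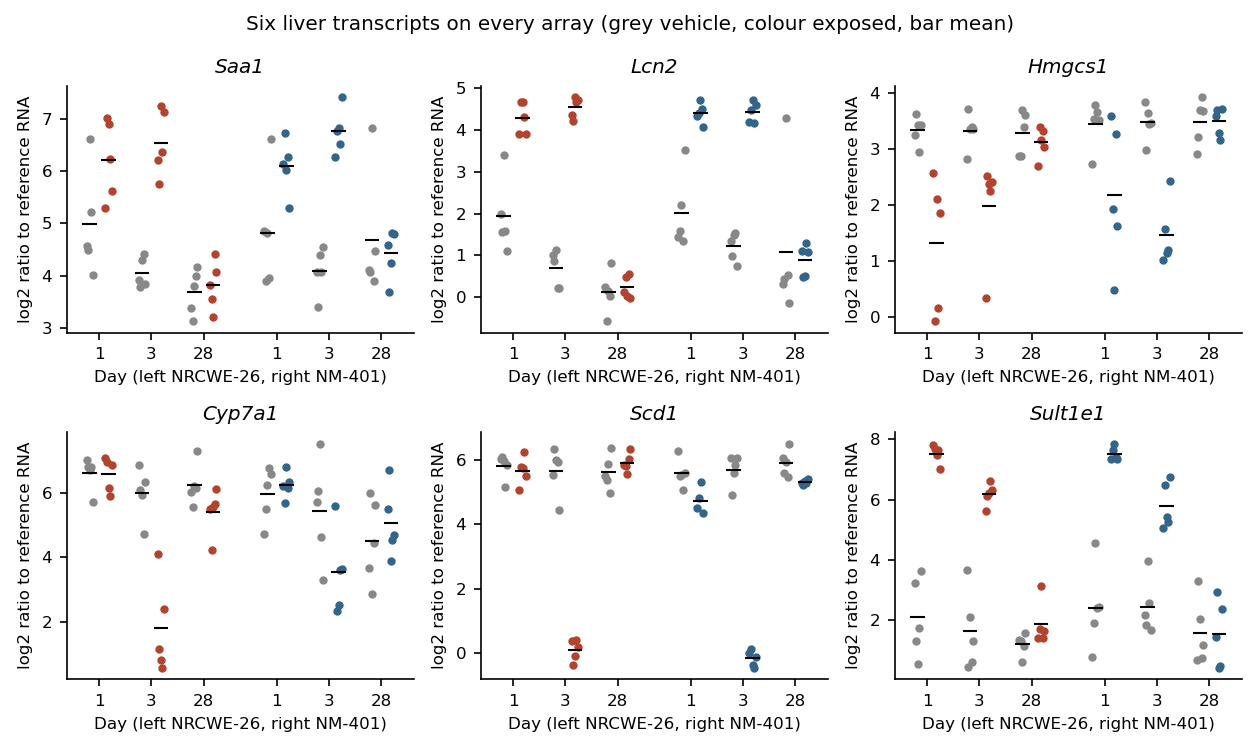
Points are the log2 ratio of liver RNA to reference RNA on single arrays for Saa1, Lcn2, Hmgcs1, Cyp7a1, Scd1 and Sult1e1, with grey for vehicle arrays, colour for exposed arrays and bars for group means of 5 arrays (4 for Scd1 on day 1 after NM-401). Scd1 at day 3 lay −5.54 (NRCWE-26) and −5.84 (NM-401) from its vehicle mean, and no gene shown passed at day 28.

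By day 28 after NRCWE-26 no reported gene of the acute phase and cholesterol panel passed. Saa1 stood at 0.12 ± 0.43, Saa2 at −0.06 ± 0.49, Saa3 at 0.16 ± 0.28, Lcn2 at 0.11 ± 0.43, and Orm2 at 0.22 ± 0.23. Hmgcs1 was at −0.17 ± 0.39, Sqle at −0.49 ± 0.36, Srebf2 at 0.18 ± 0.21, Cyp7a1 at −0.83 ± 0.60 and Abca1 at 0.04 ± 0.13. The genes that passed included genes of the circadian clock and its output: Dbp was 11.2-fold lower (−3.48 ± 0.89), Per1 3.85-fold (−1.94 ± 0.40), Tef 3.04-fold (−1.60 ± 0.34) and Per3 2.02-fold (−1.01 ± 0.22). In the clock list 6 of 16 fell and 0 rose. The deubiquitinase Usp2 (−2.71 ± 0.71), the clock-driven gene Noct (−2.44 ± 0.66) and the kinase Plk3 (−2.02 ± 0.33) were also lower. Pdk4, which restrains pyruvate oxidation, was higher (1.76 ± 0.50), as were Vapb (1.34 ± 0.17, in 1 of its 2 probes), Lrfn3 (1.24 ± 0.32), Lgalsl (2.29-fold) and Clpx (2.29-fold). All 12 of these calls ended when the NM-401 vehicle arrays of the same day served as control, and with the clock covariates Pdk4, Lrfn3, Lgalsl, Clpx, Usp2 and Noct turned sign.

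Against its own vehicle group NRCWE-26 at day 28 gave 759 genes (164 higher, 595 lower, 189 by at least 1.5-fold), 1620 with slide as a block, 302 with the clock covariates and 347 without the arrays that held pancreatic markers. It gave 0 by limma against the NM-401 vehicle group (889 at an unadjusted p under 0.05). Camera called 3 of 31 lists, the first being the clock list at −0.59 (adjusted p = 3.70e-05, 0.0390 with an estimated correlation, within slides −0.90 to −0.15). Kupffer cell and macrophage markers were at 0.39 with 0 of 11 genes passing (3.28e-04, adjusted p = 0.962 with an estimated correlation, within slides −0.04 to 0.88), and pancreatic acinar markers at 1.36 with 0 of 11 passing (0.0184, adjusted p = 0.962 with an estimated correlation, 0.0900 with slide as a block, within slides −0.27 to 5.44). Pancreatic markers were high in 2 of the 5 exposed arrays of this group and in 0 of its vehicle arrays. The acute phase list stood at 0.14 (adjusted p 0.349) and cholesterol synthesis at −0.21 (0.385).

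The same questions were asked of the long nanotube. On day 1 after NM-401, 10 of 33 acute phase genes rose and 0 fell: Lcn2 was 5.27-fold higher (2.40 ± 0.43), Orm3 5.12-fold (2.35 ± 0.36) and Stat3 2.05-fold (1.04 ± 0.16). Saa1 rose by 1.27 ± 0.43 (adjusted p 0.0267) and Saa2 by 1.99 ± 0.52 in the 4 exposed arrays that measured it. These calls ended with the clock covariates and without arrays with pancreatic markers. Vehicle replicate 5 lay high, at 6.61 in Saa1 (exposed arrays 5.30 to 6.72) and −0.42 in Saa3. The reference channel rose by 2.62, 1.91 and 1.79 for Saa1, Saa2 and Lcn2, beside Cy5 changes of 3.92, 4.00 and 4.23. Saa3 (−0.26 ± 0.28) and Orm2 (0.58 ± 0.25, 4 exposed arrays) did not pass. Cholesterol synthesis genes fell in 12 of 25 cases and rose in 0, with Sc5d at −2.08 ± 0.18, Nsdhl at −1.29 ± 0.19 and Acat2 at −1.13 ± 0.12. Hmgcs1 changed by −1.27 ± 0.39, a call ended by the clock covariates. Sqle (−0.45 ± 0.36), Srebf2 (0.15 ± 0.21), Cyp7a1 (0.28 ± 0.60) and Abca1 (0.23 ± 0.13) did not pass. The lysosomal cholesterol transporter Npc1 rose by 1.59 ± 0.16 and Mylip by 0.63 ± 0.10, and Abcg8 changed by −1.32 ± 0.23, in an efflux list with 4 of 21 up and 4 down. Among bile acid genes 1 of 19 rose, Nr1h4 (0.61 ± 0.12), and 4 fell, with Hsd3b7 at −1.19 ± 0.13.

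The largest rises on day 1 after NM-401 were in Sult1e1 (34.3-fold), Plin4 (15.4-fold), Cidec (14.6-fold), Eif4ebp3 (10.4-fold) and the growth regulator Cgref1 (6.01-fold). Etnppl, which degrades phosphoethanolamine, was 8.16-fold and Rnf186 7.57-fold lower. The pancreatic genes Reg2 (at least 7.61-fold lower) and Cela1 (at least 8.26-fold lower) and the kallikrein gene Klk1b5 (7.40-fold lower) also passed, with calls that ended under several settings. High pancreatic markers were measured in 2 of the 5 vehicle arrays of this comparison. Fatty acid synthesis genes fell in 10 of 19 cases and rose in 0, with Srebf1 6.22-fold, Fasn 4.47-fold and Acss2 4.15-fold lower. PPARα targets rose in 13 of 26 cases and fell in 0, with Cpt1a at 1.21 ± 0.14 and Acadl at 0.91 ± 0.11. Interferon genes fell in 17 of 20 cases, with Isg15 at −1.30 ± 0.13, Igtp at −1.26 ± 0.17 and Irgm1 at −0.74 ± 0.10. Of 19 unfolded protein response genes 8 rose and 2 fell, with Manf at 1.11 ± 0.26 and Xbp1 at 0.61 ± 0.14. Markers of Kupffer cells and macrophages fell in 7 of 11 cases, with Clec4f at −1.53 ± 0.29, Adgre1 at −1.07 ± 0.19 and Lyz2 at −1.05 ± 0.21. Clec4f was not called with the scanner's processed signals and Lyz2 not with the other vehicle group. Matrix genes fell in 6 of 12 cases, with Col3a1 at −1.54 ± 0.24. B cell markers fell in 3 of 6 cases, with Blnk at −0.91 ± 0.17, and endothelial markers in 3 of 9 with 1 up, with Cdh5 at −0.99 ± 0.16 and Oit3 at −0.72 ± 0.13. The complement gene C6 (−1.32 ± 0.24) and the coagulation gene F11 (−1.15 ± 0.23) were lower, but C6 was not called against the other vehicle group and F11 turned to 0.17 with the scanner's processed signals, which also ended the call of Cdh5.

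At day 1 after NM-401 5165 genes passed (2134 higher, 3031 lower, 1715 by at least 1.5-fold), 3017 with the clock covariates, and camera called 9 lists (3 higher, 6 lower), none with an estimated correlation. The acute phase list moved by 0.64 (adjusted p = 4.03e-06, 0.523 with an estimated correlation, within slides −0.08 to 1.09, 16 genes adjusted over the list alone). Cholesterol synthesis moved by −0.74 (7.61e-07, adjusted p = 0.523 with an estimated correlation, within slides −1.94 to 0.52, 13 adjusted over the list alone), so that each of these had the opposite sign on a slide. Interferon genes moved by −0.89 (5.18e-15, adjusted p = 0.101 with an estimated correlation, within slides −1.30 to −0.58). PPARα targets moved by 0.70 (2.87e-10, adjusted p = 0.101 with an estimated correlation, within slides 0.42 to 1.17). Fatty acid synthesis moved by −0.96 (3.78e-09, adjusted p = 0.159 with an estimated correlation, within slides −1.18 to −0.65). Kupffer cell markers moved by −0.69 (2.03e-04, adjusted p = 0.460 with an estimated correlation, within slides −0.91 to −0.42). Matrix genes moved by −0.55 (2.94e-04, adjusted p = 0.460 with an estimated correlation, within slides −1.14 to −0.33), and by −0.37 (0.0119) without NM-401 vehicle day 1 replicate 3, which stood apart for this list and held high pancreatic markers (6.03). The unfolded protein response moved by 0.33 (0.00815, adjusted p = 0.523 with an estimated correlation, within slides 0.22 to 0.57). Pancreatic acinar markers moved by −2.15 with 0 of 11 genes passing (0.0250, adjusted p = 0.675 with an estimated correlation, 0.0738 with slide as a block, within slides −5.42 to 0.07). Endothelial markers, at −0.27, passed with slide as a block (0.0280) but not without it (0.0713), and lay between −0.30 and −0.21 within slides. Adipocyte markers stood at −0.84 (0.235) and lung epithelium markers at −0.71 (0.235).

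On day 3 after NM-401, 25 of 33 acute phase genes rose and 0 fell. Lcn2 was 9.33-fold higher (3.22 ± 0.43), Saa1 6.32-fold (2.66 ± 0.43), Saa2 9.94-fold (3.31 ± 0.49) and Saa3 3.33-fold (1.74 ± 0.28). For the first 3 of these the Cy5 channel alone changed by 5.69, 6.09 and 6.42 and the reference channel rose by 2.30, 3.16 and 2.96. Steap4 rose by 2.90 ± 0.33, the copper carrier Cp by 1.39 ± 0.14, Lbp by 1.09 ± 0.13 and Orm2 by 1.01 ± 0.23, the last not called with the scanner's processed signals. Cxcl1 was 14.9-fold higher, and 8 of 15 cytokine genes rose and 0 fell, with Il1r1 at 2.12 ± 0.29, a call ended by the clock covariates, and Icam1 at 0.98 ± 0.14. The neutrophil protease gene Prtn3 was higher, with a bound of 9.90-fold on the Aquantile scale and a change of 3.18 in quantile-normalized Cy5. S100a9 (1.89 ± 0.52), S100a8 (1.45 ± 0.43) and Retnlg (0.67 ± 0.18) were the 3 of 7 neutrophil markers that rose, calls that ended with the clock covariates. Mt2 rose by 3.45 ± 0.59, a call ended by the clock covariates. Mt1 was 7.26-fold higher by ratio, with Cy5 up by 1.46 and the reference channel at −1.39, and for Mt2 these were 2.29 and −1.17. Slc39a14 rose by 1.75 ± 0.21 and the zinc importer Slc39a4 changed by −1.12 ± 0.11. Complement and coagulation genes rose in 6 of 23 cases and fell in 0.

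Scd1 was again the gene with the largest fall on day 3 after NM-401, 57.3-fold lower (95% interval 40.1 to 81.7, −5.84 ± 0.26). All 19 fatty acid synthesis genes fell, with Fasn 8.93-fold and Me1 4.97-fold lower, and the related desaturase Scd3 was lower in 2 of its 3 probes. The bound for Scd3 was 14.02-fold on the Aquantile scale, while its quantile-normalized Cy5 changed by −3.56. Cholesterol synthesis genes fell in 19 of 25 cases and rose in 0: Hmgcs1 was 4.01-fold lower (95% interval 2.32 to 6.92), Sc5d 4.17-fold, Nsdhl 2.63-fold and Pmvk 2.69-fold. Sqle (−0.90 ± 0.36, adjusted p = 0.0865) and Srebf2 (0.07 ± 0.21) did not pass. Abca1 rose by 0.50 ± 0.13, a call ended by the clock covariates, Lrp1 by 0.95 ± 0.10 and Lcat by 0.99 ± 0.14, in an efflux list with 5 of 21 up and 3 down. Bile acid genes fell in 6 of 19 cases and rose in 0, with Hsd3b7 at −1.27 ± 0.13, Cyp8b1 at −1.30 ± 0.34 and Cyp7a1 at −1.90 ± 0.60 (adjusted p 0.0228). The Cyp7a1 and Cyp8b1 calls ended with the clock covariates and with the scanner's processed signals. Of 15 NRF2 targets 8 fell and 1 rose, with Gsta2 12.0-fold, Gstm3 4.09-fold and Gstm1 3.42-fold lower. Ces2b was 16.3-fold lower, the protein quality control gene Derl3 10.8-fold higher and Sult1e1 10.2-fold higher. Unfolded protein response genes rose in 12 of 19 cases and fell in 1, with Calr at 0.72 ± 0.11 and Sdf2l1 at 1.22 ± 0.23. Interferon genes split, with 5 of 20 up, among them the regulator Irf7 (1.11 ± 0.18), and 2 down, among them Cxcl9 (−1.56 ± 0.30), whose call ended with the clock covariates. Stellate cell markers fell in 4 of 9 cases, with Pdgfrb at −0.60 ± 0.14 and Rgs5 at −1.08 ± 0.30, calls that ended with the clock covariates.

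In all, 3889 genes passed at day 3 after NM-401 (1785 higher, 2104 lower, 1411 by at least 1.5-fold), 1802 with the clock covariates, and camera called 11 lists (5 higher, 6 lower), 3 of them with an estimated correlation. Those 3 were fatty acid synthesis at −1.78 (adjusted p = 8.02e-31, 5.86e-04 with an estimated correlation, within slides −1.89 to −1.60) and the acute phase list at 1.33 (1.02e-24, 0.0354 with an estimated correlation, within slides 1.13 to 1.48), followed by NRF2 targets at −0.72 (2.42e-07, 0.0354 with an estimated correlation, within slides −0.88 to −0.59). Cholesterol synthesis moved by −1.07 (1.53e-16, adjusted p = 0.0996 with an estimated correlation, within slides −1.52 to −0.49, 22 genes adjusted over the list alone). The unfolded protein response moved by 0.55 (2.63e-07, adjusted p = 0.0996 with an estimated correlation, within slides 0.18 to 0.98). Cytokines moved by 0.63 (2.58e-05, adjusted p = 0.0996 with an estimated correlation, within slides 0.38 to 0.96, ended by the clock covariates). Complement genes moved by 0.42 (1.14e-04, adjusted p = 0.478 with an estimated correlation, within slides 0.27 to 0.49). Stellate cell markers moved by −0.55 (0.00112, adjusted p = 0.199 with an estimated correlation, within slides −0.85 to −0.29, ended by the clock covariates). PPARα targets moved by 0.31 (0.00215, adjusted p = 0.478 with an estimated correlation, within slides −0.03 to 0.76). Bile acid genes moved by −0.54 (0.00897, adjusted p = 0.525 with an estimated correlation, within slides −0.98 to −0.31, ended by the clock covariates and the scanner's processed signals). Matrix genes moved by −0.33 (0.0418, adjusted p = 0.618 with an estimated correlation, within slides −0.79 to 0.14).

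At day 28 after NM-401 limma called 0 genes (smallest adjusted p 0.160), against 1052 at an unadjusted p under 0.05, and 1 gene passed with slide as a block, scan day or array weights, with the scanner's processed signals or with the Cy5 channel alone. With both vehicle groups pooled 13 genes passed, and against the NRCWE-26 vehicle group 449. Saa1 stood at −0.25 ± 0.43, Saa2 at −0.50 ± 0.49, Saa3 at −0.18 ± 0.28, Lcn2 at −0.20 ± 0.43, and Orm2 at −0.08 ± 0.23. Without NM-401 vehicle day 28 replicate 3, which was high for Saa1, Saa3 and Lcn2, these 5 turned to 0.29, 0.10, 0.15, 0.60 and 0.14, and none passed. Hmgcs1 was at 0.01 ± 0.39, Sqle at −0.07 ± 0.36, Srebf2 at −0.02 ± 0.21, Cyp7a1 at 0.54 ± 0.60 and Abca1 at −0.20 ± 0.13. Camera called 6 lists with 0 members passing, and neither fry nor an estimated correlation called any. They were interferon genes (mean −0.24, adjusted p = 1.66e-07, 0.389 with an estimated correlation, within slides −0.56 to 0.03) and heat shock genes (−0.23, 1.56e-04, adjusted p = 0.187 with an estimated correlation, within slides −0.46 to −0.04). Next came fatty acid synthesis (−0.21, 0.00603, adjusted p = 0.845 with an estimated correlation, within slides −0.49 to −0.01) and neutrophil markers (−0.39, 0.00603, adjusted p = 0.440 with an estimated correlation, within slides −1.67 to 0.15). Without the same vehicle replicate 3 the neutrophil shift was −0.08 (0.851) and not called, and heat shock, fatty acid synthesis and interferon stood at −0.140 (0.0326), −0.310 (8.00e-06) and −0.335 (6.21e-13). The last were B and plasma cell markers (0.20, 0.0105, adjusted p = 0.299 with an estimated correlation, within slides 0.11 to 0.40) and clock genes (0.20, 0.0229, adjusted p = 0.389 with an estimated correlation, 0.0520 with slide as a block, 0.115 without that array, within slides −0.01 to 0.35). The acute phase list stood at −0.13 (adjusted p 0.130), and without that array at 0.137 with a call (0.0217), and cholesterol synthesis at 0.00 (0.988).

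**Figure D3:**
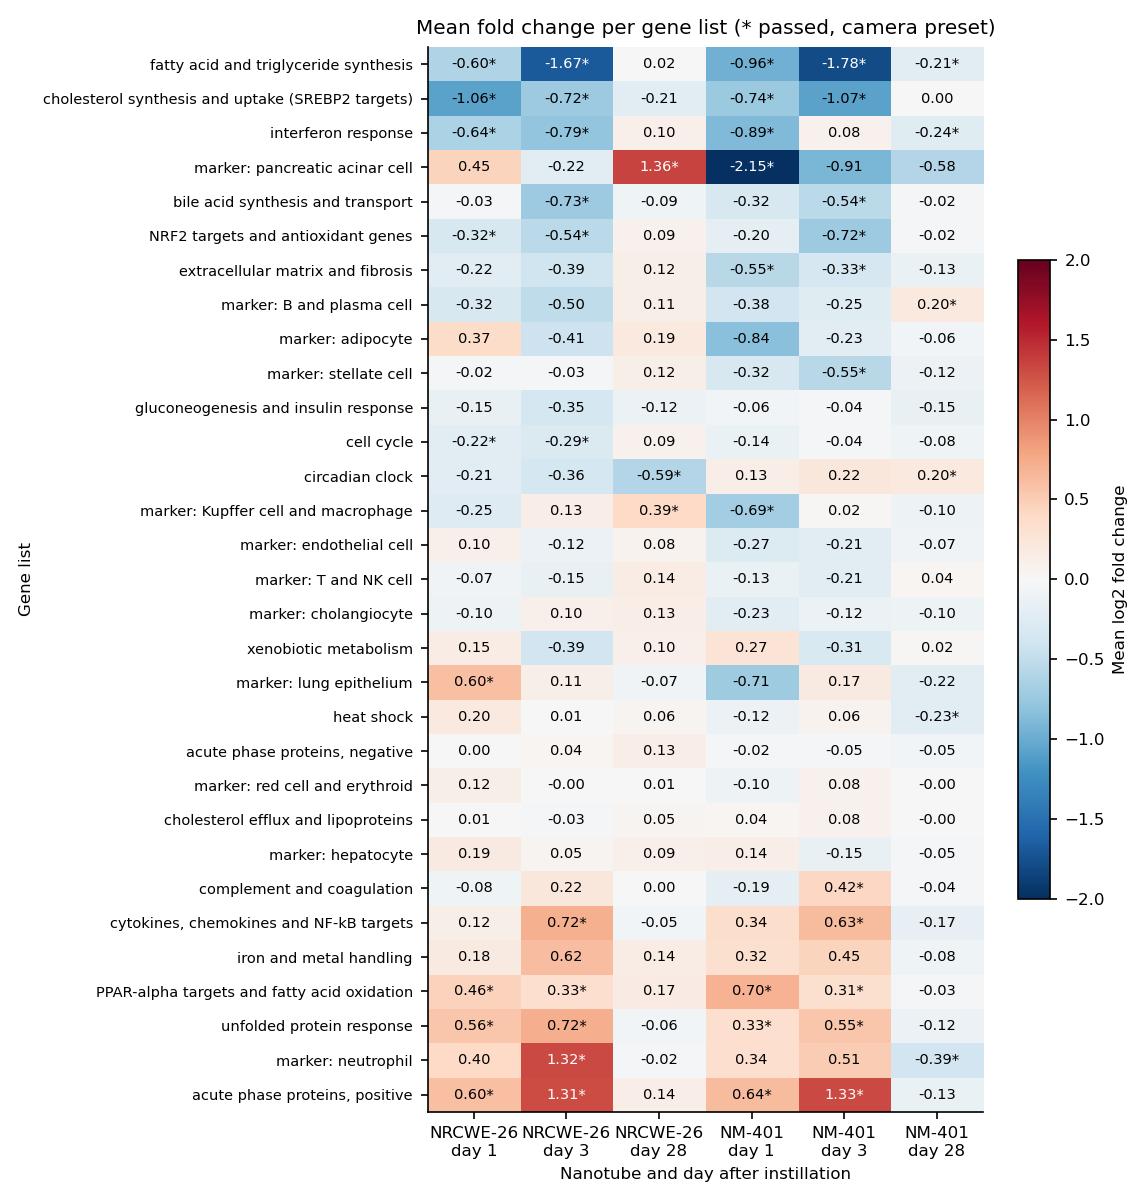
The heat map gives the mean log2 difference from vehicle of the members of each of 31 gene lists (vertical) in the 6 comparisons (horizontal), with an asterisk where camera with its preset correlation passed. Fatty acid synthesis reached −1.67 and −1.78 and the acute phase list 1.31 and 1.33 on day 3.

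In none of the 6 comparisons did camera call 11 of the lists in the main setting, which were negative acute phase proteins, cholesterol efflux, gluconeogenesis, drug metabolism, iron handling, and the markers of T and NK cells, endothelium, bile duct cells, red cells, adipocytes and hepatocytes. Single genes within them passed: Igfbp2, an insulin-like growth factor binding protein, changed by −1.71 ± 0.21 and −1.35 ± 0.21 on day 3 (NRCWE-26 and NM-401). The cytochrome gene Cyp3a13 rose in all 4 comparisons of days 1 and 3, by 1.56 ± 0.22, 1.77 ± 0.22, 1.45 ± 0.22 and 1.65 ± 0.22. Cyp2c55 changed by −1.92 ± 0.19 on day 3 after NRCWE-26 and was at least 3.00-fold lower after NM-401. Heat shock genes went both ways after NRCWE-26, with 4 of 11 up and 2 down on day 1, among them the chaperone Hspa8 at 0.77 ± 0.16.

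The effects of both particles, each against its own vehicle arrays, were then set side by side across the 26084 features. On day 1 Pearson's r of the log2 changes was 0.676 and Spearman's rho 0.551, and on day 3 they were 0.764 and 0.588; these are across genes, which are not independent replicates. On day 1 1528 genes rose after both particles, against 284 for independent lists, and 1718 fell, against 374, while 36 passed in opposite directions. The day 3 counts were 1219 (against 182), 1459 (against 262) and 10. On day 28 r was −0.172 and turned to 0.0332 with the clock covariates. Direct tests of the difference between the particles called 362 genes on day 1 (97 higher after NM-401, 265 lower), 121 on day 3 (78 and 43) and 286 on day 28 (232 and 54). With 1 array left out these counts ranged from 210 to 552, 36 to 278 and 165 to 286. With slide as a block these were 1740, 406 and 928, and with the clock covariates 127, 41 and 106. On day 1 the share that was higher, 26.8%, moved to 42.5% with the scanner's processed signals, 46.3% with the series matrix and 56.4% with the Cy5 channel alone.

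Interferon genes differed most between the particles on day 3, and were the 1 of 7 lists that camera also called with an estimated correlation. Their change after NM-401 lay above that after NRCWE-26 by 0.87 on average, with 9 of 20 passing singly and 17 adjusted over the list alone (camera adjusted p = 3.67e-28, 0.00483 with an estimated correlation, 2.61e-26 with slide as a block). Neutrophil markers lay lower after NM-401 by 0.80 in size (mean −0.80, 1.84e-04, adjusted p = 0.216 with an estimated correlation), and Retnlg by −1.17. Single genes with large differences on day 1 were Rnu1b6 (2.74 ± 0.25), the pantetheinase Vnn1 (1.84), the small nucleolar RNA Snora47 (1.84), the ileal bile acid transporter Slc10a2 (−2.50), the neurotrophin receptor Ntrk2 (−2.40) and the sulfotransferase Sult5a1 (−2.37). On day 3 they were Ppp1r3g (3.06), Plk3 (1.96), Rnu1b6 (1.93), the manganese exporter Slc30a10 (−1.90) and Ngfr (−1.28), and on day 28 Dbp (5.40 ± 1.26), the protease Pcsk4 (2.47), Tef (2.31), Lgalsl (−1.70), Desi2 (−1.12) and Vapb (−1.09). The calls of Plk3, Slc30a10 and Ngfr on day 3 and of Dbp, Lgalsl and Desi2 on day 28 ended when a single array was left out, and Lgalsl turned to 0.0502 with the clock covariates. The vehicle groups contributed to these values to differing degrees. Between the exposed groups alone Rnu1b6 and Snora47 differed by 0.73 and 0.27 on day 1, Ppp1r3g, Plk3 and Rnu1b6 by 0.81, 0.53 and 0.02 on day 3, and Dbp, Pcsk4, Tef and Vapb by 2.38, 0.47, 0.89 and 0.09 on day 28. On day 28 limma called 0 genes between the exposed groups and 775 between the vehicle groups. The interferon difference of day 3 was 0.75 between the exposed groups and −0.12 between the vehicle groups. Lung epithelium markers differed by −1.31 on day 1 (1.65e-05, 0.0274 with an estimated correlation) and pancreatic markers by −2.60 (0.00145, adjusted p = 0.774 with an estimated correlation). Between the exposed groups these were −0.68 and −0.51 and between the vehicle groups 0.62 and 2.10.

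**Figure D4:**
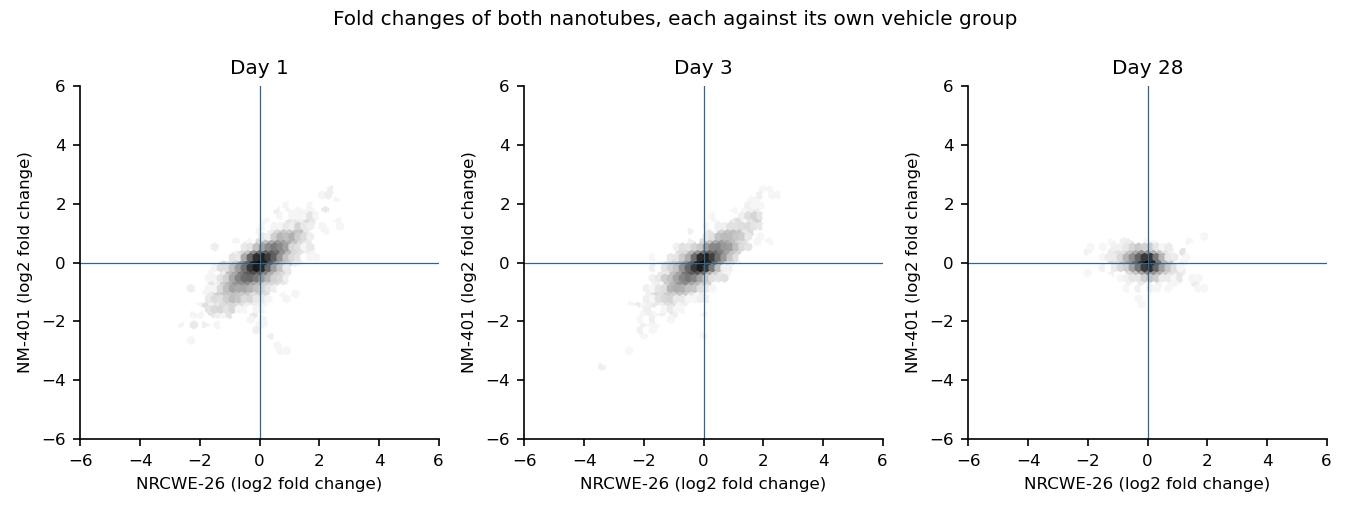
Each panel sets the log2 difference from vehicle after NRCWE-26 (horizontal) against that after NM-401 (vertical) for 26084 features on days 1, 3 and 28, with shading for the number of features. Pearson's r was 0.676, 0.764 and −0.172.

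How the effects moved over time was tested as the difference of each day's effect from that of day 1. After NRCWE-26 2923 genes differed on day 3 (1149 higher, 1774 lower) and 4036 on day 28 (1719 and 2317); after NM-401 2155 (1190 and 965) and 2779 (1534 and 1245) did. With slide as a block these counts were 4699, 6158, 3587 and 4278, and with the clock covariates the last was 1202. From day 1 to day 3 after NRCWE-26 Cxcl1 (3.76), Mt2 (3.63) and Slc41a2 (3.39) moved up and Scd1 (−5.39), Cyp7a1 (−4.15) and the calcium-binding gene Cib3 (−4.06) moved down. After NM-401 Prtn3 (2.99), the organic anion carrier Slc22a26 (2.50), the complement gene C8a (2.46) and Saa3 (3.99-fold) moved up and Scd1 (−4.99), Ces2b (−4.01) and Gsta2 (−3.52) down, with Slc22a26 and C8a not called with the scanner's processed signals. Between days 1 and 28 the named genes moved against their day 1 effects: after NRCWE-26 Sult1e1 (−4.76), Plin4 (−4.54), Cidec (−4.51) and Lcn2 (−2.26) moved down and Aqp8 (3.90), Rnf186 (3.44), Ccnd1 (3.13) and Hmgcs1 (1.84) up, the last a call that ended when a single array was left out. After NM-401 Sult1e1 (−5.16), Cidec (−4.13), Plin4 (−4.10), Lcn2 (−2.60) and Saa2 (−2.49) moved down and Rnf186 (3.69), Etnppl (3.52) and the organic anion transporter Slco1a1 (3.52) up. Without NM-401 vehicle day 28 replicate 3 Lcn2 stood at −1.79 and Saa2 at −1.89, the latter no longer called (adjusted p 0.0544).

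The vehicle groups of both particles received the same liquid and were compared on each day. Clock genes differed in their group means: in the NRCWE-26 vehicle groups the log2 ratio of Dbp was 2.88 ± 0.06 (SD, n = 5) on day 1, 2.73 ± 0.10 on day 3 and 1.83 ± 1.02 on day 28. In the NM-401 vehicle groups it was −0.00 ± 2.29, −0.71 ± 3.09 and −1.20 ± 1.94. Arntl, the clock activator whose level runs opposite to Dbp, was −1.91 ± 0.20, −2.15 ± 0.43 and −1.08 ± 1.04 in the first and 0.11 ± 1.86, 0.17 ± 2.11 and 0.63 ± 0.41 in the second. The NM-401 vehicle groups were split: Dbp lay at 2.41 and 2.48 or at −2.38 to −0.93 on day 1. On day 3 it lay at 2.63 and 2.72 or at −3.21 to −2.71. In Dbp the higher arrays lay near NRCWE-26 vehicle arrays. Neither Dbp nor Arntl passed on every day, but 22 features did, with 1 sign each. The tests called 428 genes on day 1 (250 higher in the NM-401 vehicle group, 178 lower), 146 on day 3 (70 and 76) and 775 on day 28 (156 and 619). With 1 array left out they ranged from 133 to 772, 19 to 439 and 480 to 823. Large differences were in the steroid dehydrogenase gene Hsd3b5 (1.94), the repressor Bcl6 (1.89), Slc13a2 (1.67), Rgs16 (−3.12), Usp2 (−2.96) and Ppp1r3g (−2.03) on day 1. On day 3 Bcl6 (2.36), Arntl (2.33), Tubb2a (1.85), Ppp1r3g (−2.25), Pcsk4 (−2.06) and Rnu1b6 (−1.91) led, and on day 28 A1bg (2.77), Slc41a2 (1.44), Tubb2a-ps2 (1.33), Dbp (−3.03), Pcsk4 (3.99-fold lower) and Rnu1b6 (−1.76). Some of these calls ended when a single array was left out: Hsd3b5, Bcl6 and Usp2 on day 1, Bcl6, Arntl, Tubb2a and Pcsk4 on day 3, and A1bg, Slc41a2, Tubb2a-ps2 and Dbp on day 28. Without NM-401 vehicle day 28 replicate 3 A1bg stood at 2.66 (adjusted p 0.0756), Slc41a2 at 0.91 (0.209) and Dbp at −2.62 (0.170). With the clock covariates 33, 6 and 366 genes passed, with slide as a block 1423, 472 and 1732, and without the arrays that held pancreatic markers 29 and 11 on days 1 and 3. The day 1 share that was higher, 58.4%, moved to 48.0% with the series matrix and 41.0% with the Cy5 channel alone. The clock list differed by −0.43, −0.50 and −0.46 (camera adjusted p 1.46e-04, 8.76e-05 and 2.20e-04, 0.0931, 0.0558 and 0.0750 with an estimated correlation).

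**Figure D5:**
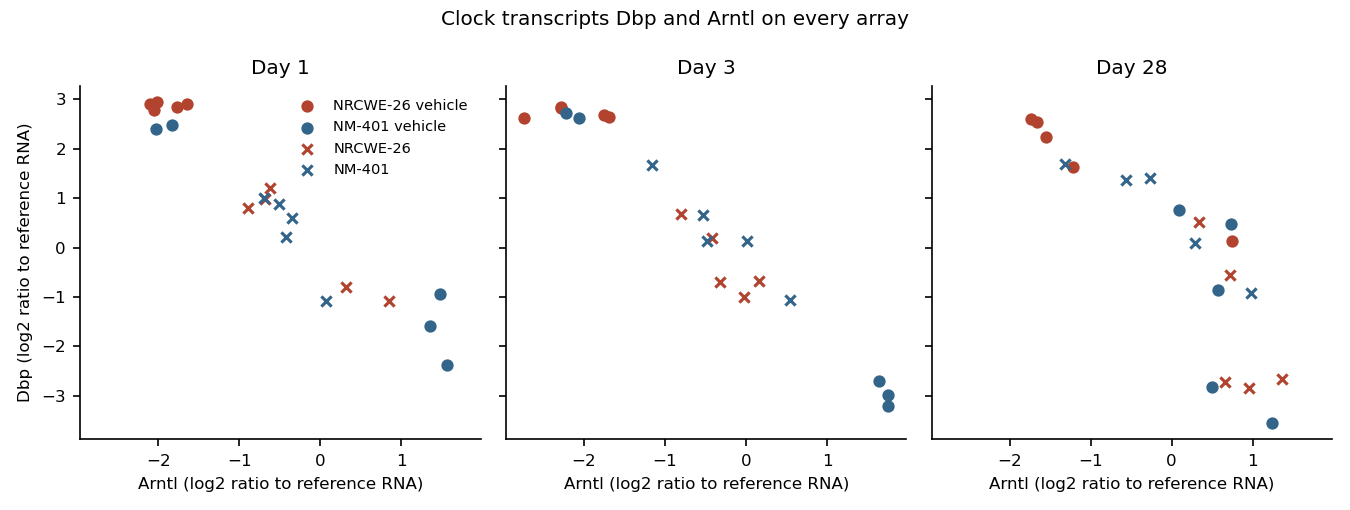
Each point is 1 array, with the log2 ratio to reference RNA of Arntl (horizontal) and Dbp (vertical), by day, with circles for vehicle and crosses for exposed arrays in the colour of their particle. The 5 NRCWE-26 vehicle arrays of day 1 lie close together (Dbp 2.88 ± 0.06), while the 5 NM-401 vehicle arrays of that day spread from −2.38 to 2.48 in Dbp.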

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

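Of the tests in this part, the slide tests, the comparison of exposed with vehicle arrays for pancreatic genes, the test of genes that rise in fasting, the clock covariates and the change of vehicle group were chosen only after results had been seen; the predictions for the clock, vehicle and pancreatic list tests were written before their values were known.

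After NRCWE-26, 759 genes passed at day 28, led by clock genes such as Dbp, while NM-401 gave 0. With slide as a block 1620 passed, which argues against slide as the cause. With the NM-401 vehicle arrays as control 0 passed (889 unadjusted), as predicted if the NRCWE-26 vehicle arrays stand apart. The 759 genes' median change went from 0.432 to 0.0519, with 526 keeping their sign. They were picked against NRCWE-26 vehicle arrays, so this decides nothing. With clock components as covariates 302 passed (median 0.368), between the bounds set in advance. Clock phase thus cannot be told apart from a late effect of exposure. A candidate explanation is that mice were collected at differing times of day, which collection records could test. This need not concern the NRCWE-26 vehicle mice alone, since Dbp also ranged widely within other groups of day 28. It ran from −3.55 to 0.77 in the NM-401 vehicle group and from −2.84 to 0.53 in NRCWE-26 exposed mice.

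Pancreatic acinar genes were high in 9 arrays, with a list mean of 2.01 to 6.65 against a median of 0.665 in the other 51. Of a second list of 12 pancreatic genes not used to pick these arrays, 100% were higher in them by 1 or more. Try4 and Try5 stood at 6.27 and 6.02 and Pnlip of the first list at 5.76. Pancreatic tissue in some samples would give this. Since the signal filter could let genes in through these 9 arrays alone, that share is no independent test. Of the 9 arrays 4 were from exposed and 5 from vehicle mice (Fisher's exact p = 1, two-sided), which argues against exposure as the cause. The amylase gene Amy2a5 was high in the other arrays too (5.15), so the liver or the probe gives signal for 1 of the 11 listed genes.

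Genes of fatty acid synthesis fell on day 3 after both particles. With the clock covariates the list mean kept a ratio of at least 0.801 (−1.39 after NRCWE-26 and −1.43 after NM-401, adjusted p 3.31e-15 and 5.41e-18), which argues against clock phase as the whole cause, and the highest within-slide mean was −1.57, which argues against slide. Lower food intake stays open: 7 genes that rise in fasted liver differed by −0.12 (95% interval −0.52 to 0.27, exact permutation p = 0.706) after NRCWE-26 and 0.16 (−0.24 to 0.555, exact permutation p = 0.405) after NM-401, and the upper bound of 0.555 was not under the limit of 0.5 set for that test. The fall may be a response to exposure, a hypothesis found and tested on the same data, and pair-fed vehicle mice could test it.

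Chance was examined with 100 splits of the same arrays, the real one included, and the highest count among the other splits is given after each real count. For genes in the counts that follow, only the real split gave as many, the smallest share that 100 splits can give. Taken singly, without correction for the number of counts, this argues against chance. It holds for NRCWE-26 on days 1 (6690, other splits up to 2863), 3 (5916, 2817) and 28 (759, 63). For NM-401 it holds on days 1 (5165, 2468) and 3 (3889, 1528), and for the particles on days 1 (362, 104) and 28 (286, 2). The same holds for the differences from day 1 (2923 and 2715, 4036 and 528, 2155 and 584, 2779 and 2607) and for the vehicle groups (428 and 77, 146 and 111, 775 and 93). On day 3 the particles' 121 genes were reached in 2 splits (up to 130), a share under the 0.05 set in advance. Another split exceeded the real count, and with 1 array left out the count ran from 36 to 278. Chance is therefore not excluded there. For NM-401 on day 28 the splits decide nothing, since any count reaches a real count of 0 (all 100 splits, up to 7). For list counts all shares exceeded the 0.05 limit, so chance is not excluded. Other splits may keep part of a real difference. The 9, 11 and 3 lists after NRCWE-26 were reached in 19, 62 and 77 splits (others' median 6, 12 and 4, up to 13, 19 and 12). After NM-401 9, 11 and 6 were reached in 47, 39 and 66 (8, 9 and 7, up to 16, 18 and 18). These calls used a preset correlation, and 44 of 49 ended with an estimated one.

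Single arrays far from the other 4 of their group were found in 29 of 312 groups of 5 values (ratio of the gap to the range above 0.71), and chance gives about 1 in 20 such groups. High single arrays were found at NM-401 vehicle day 28 replicate 3 for Saa1 (0.804), Saa3 (0.785) and Lcn2 (0.845). NM-401 vehicle day 1 replicate 3 was apart for Plin4 (0.878), Cidec (0.748) and matrix genes (0.783), its replicate 1 for Hmgcs1 (0.738) and cholesterol synthesis (0.711), and its replicate 4 for fatty acid synthesis (0.764). NRCWE-26 vehicle day 1 showed Orm2 (0.731, replicate 3), Aqp8 (0.815, replicate 4) and Cyp7a1 (0.761, replicate 5). NRCWE-26 vehicle day 3 showed Saa3 (0.795, replicate 4), neutrophil markers (0.711, replicate 3) and PPARα targets (0.757, replicate 5, but 0.613 over the 25 of 26 members measured on all 5 arrays). NRCWE-26 day 1 showed Saa3 (0.776, replicate 3), Bmper (0.778, replicate 2) and Ccnd1 (0.758, replicate 3). NRCWE-26 day 3 replicate 1 was lowest for Hmgcs1 (0.878), Sqle (0.807), cholesterol synthesis (0.856) and neutrophil markers (0.813), and replicate 5 highest for fatty acid synthesis (0.811). NRCWE-26 day 28 showed Pdk4 (0.794, replicate 2) and pancreatic markers (0.749, replicate 5). NM-401 day 1 showed Srebf2 (0.753, replicate 3) and the acute phase list (0.895, replicate 5, lowest), where replicate 5 lacked Saa2 and Orm2 and the ratio was 0.798 over the 29 of 33 members measured on all 5 arrays. Also apart at NM-401 day 3 were Mt2 (0.792, replicate 1) and stellate cell markers (0.743, replicate 2).

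Differences between groups that passed a direct test came next. Effects of the particles differed in 362, 121 and 286 genes on days 1, 3 and 28, and effects of days 3 and 28 differed from day 1 in 2923 and 4036 genes after NRCWE-26 and 2155 and 2779 after NM-401. Between particles (NM-401 minus NRCWE-26) the day 1 differences were Rnu1b6 2.74, Vnn1 1.84, Snora47 1.84, Slc10a2 −2.50, Ntrk2 −2.40 and Sult5a1 −2.37. Those of day 3 were Ppp1r3g 3.06, Plk3 1.96, Rnu1b6 1.93, Slc30a10 −1.90, Ngfr −1.28 and Retnlg −1.17, and those of day 28 Dbp 5.40, Pcsk4 2.47, Tef 2.31, Lgalsl −1.70, Desi2 −1.12 and Vapb −1.09. Differences between the vehicle groups enter these values, as given above. Lists that differed, also with an estimated correlation, were lung epithelium markers by −1.31 on day 1, interferon genes by 0.871 on day 3 and clock genes by 0.787 on day 28 (0.323 between the exposed groups and −0.464 between the vehicle groups). Differences from day 1 after NRCWE-26 were Cxcl1 3.76, Mt2 3.63, Slc41a2 3.39, Scd1 −5.39, Cyp7a1 −4.15 and Cib3 −4.06 on day 3 and Aqp8 3.90, Rnf186 3.44, Ccnd1 3.13, Hmgcs1 1.84, Sult1e1 −4.76, Plin4 −4.54, Cidec −4.51 and Lcn2 −2.26 on day 28. After NM-401 they were Prtn3 2.99, Slc22a26 2.50, C8a 2.46, Saa3 1.996, Scd1 −4.99, Ces2b −4.01 and Gsta2 −3.52 on day 3 and Rnf186 3.69, Etnppl 3.52, Slco1a1 3.52, Sult1e1 −5.16, Cidec −4.13, Plin4 −4.10, Lcn2 −2.60 and Saa2 −2.49 on day 28.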

How the results depend on the processing

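The clock covariates, the omission of arrays with pancreatic markers, the vehicle group of the other particle as control and the leave-one-out correlations were chosen after seeing the data, and the other alternatives before. Of 365 named gene calls 211 held in every setting and 301 with every array left out. Of 49 list calls 4 held in every setting and 36 with every array left out, and 44 ended with an estimated correlation. For named genes slide (fixed or random), scan day, Aquantile and single probes changed none of 404 values (365 calls and panel genes that did not pass), the series matrix ended 9, the scanner's processed signals ended 42 and turned 6, and the clock covariates ended 94 and turned 7 of 387. Mean and median pixel signals were not compared. No paired analysis was possible because the replicate numbers were given in accession order and the labels state no shared numbers, but exposed and vehicle arrays shared slides, which the slide block uses. Dim probes limit what the arrays can show. For each change listed here the cause was not tested, except that stricter thresholds and fewer arrays call fewer genes by construction.

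With a limit of 1.5-fold, 2113, 2053 and 189 genes passed after NRCWE-26 on days 1, 3 and 28 (6690, 5916 and 759 without it) and 1715 and 1411 after NM-401 on days 1 and 3 (5165 and 3889). At an adjusted p under 0.01, 316 passed after NRCWE-26 on day 28 and 2408 after NM-401 on day 3. The clock covariates gave 3249 (NRCWE-26 day 3), 302 (day 28), 3017 (NM-401 day 1) and 1802 (day 3), 127, 41 and 106 between particles (main 362, 121 and 286), 1202 for NM-401 day 28 against day 1 (main 2779), 33, 6 and 366 between vehicle groups (main 428, 146 and 775), and a correlation of the particles of 0.0332 on day 28 (main −0.172). Slide as a fixed block gave 1620 (NRCWE-26 day 28), 1 (NM-401 day 28), 1740, 406 and 928 between particles, 4699, 6158, 3587 and 4278 against day 1 (main 2923, 4036, 2155 and 2779), and 1423, 472 and 1732 between vehicle groups. As a random block slide gave 1490, 1, 1375, 398, 815, 4400 and 3375 (day 3 against day 1), 1274, 442 and 1591, and scan day 1450, 1, 1359, 324, 780, 4464, 3303, 1192, 439 and 1549 in the same order.

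Without the arrays with pancreatic markers 347 genes passed for NRCWE-26 on day 28, 174, 75 and 153 between particles, and 29 and 11 between vehicle groups on days 1 and 3. With the vehicle groups pooled there were 50 genes and 7 lists for NRCWE-26 and 13 genes and 2 lists for NM-401 on day 28, and with the other particle's vehicle group 0 genes and 10 lists and 449 genes and 2 lists. The scanner's processed signals gave 1 gene for NM-401 on day 28 and correlations of 0.572 and 0.633 on days 1 and 3 (main 0.676 and 0.764). The Cy5 channel alone gave 1, 470 between particles on day 28 and 644 between vehicle groups on day 1. Array weights gave 1, 334 and 489 between particles on days 3 and 28 and 367 between vehicle groups on day 3. With only the arrays compared there were 202 and 39 between particles on days 1 and 3 and 72, 12 and 417 between vehicle groups. No filter gave 59 and 182 between particles on days 3 and 28 and 72 between vehicle groups on day 3. Lists called with an estimated correlation numbered 0, 1 and 1 after NRCWE-26 and 0, 3 and 0 after NM-401, and fry called 1 for NRCWE-26 on day 28 and 15 and 0 for NM-401 on days 1 and 28 (main 9, 11, 3, 9, 11 and 6).

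Directions turned in these cases. With the Cy5 channel alone negative acute phase proteins moved to −0.445 (NRCWE-26 day 3), −0.283 (NM-401 day 1) and −0.236 (NM-401 day 3) and were called (adjusted p 3.13e-04, 0.0260 and 0.00212). With the other vehicle group the day 28 lists of NRCWE-26 moved to −0.206 (acute phase), −0.107 (interferon) and −0.297 (heat shock), and those of NM-401 to 0.215 (acute phase), 0.130 (heat shock), 0.209 (unfolded protein response), −0.263 (clock, −0.0310 with pooled vehicles) and 0.166 (neutrophil), with pancreatic markers at −0.0564 for NM-401 on day 1. With the scanner's processed signals Apoa4 turned to −0.171 (NRCWE-26 day 1), −0.499 (day 3) and −0.245 (NM-401 day 3), Cyp1a2 to 0.229 and 0.211 on day 3, and F11 to 0.172 (NM-401 day 1). With the other vehicle group Dbp turned to 0.222 and Slc30a10 to −0.167 (NRCWE-26 day 1), and Per1 to −0.316 and Per2 to −0.104 (NM-401 day 3). With the clock covariates the day 28 values of NRCWE-26 turned for Pdk4 (−0.0680), Lrfn3 (−0.0520), Lgalsl (−0.0981), Clpx (−0.0648), Usp2 (0.309) and Noct (0.283), and Lgalsl between particles to 0.0502. With single arrays left out, signs turned only in genes and lists that had not passed, such as Sqle at day 3 after NRCWE-26 (0.210 without NRCWE-26 day 3 replicate 1) and the acute phase list below.

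Leaving out 1 array gave 5795 to 6536, 5229 to 5962 and 454 to 725 genes for NRCWE-26 on days 1, 3 and 28, and 4254 to 5157, 3309 to 3833 and 0 to 1 for NM-401. Between particles it gave 210 to 552, 36 to 278 and 165 to 286, against day 1 2602 to 3043, 3565 to 4196, 1688 to 2235 and 2310 to 2888, and between vehicle groups 133 to 772, 19 to 439 and 480 to 823. Correlations ranged from 0.628 to 0.705, 0.7102 to 0.779 and −0.203 to −0.118, and lists from 6 to 8, 10 to 14 and 2 to 4 (NRCWE-26) and 8 to 10, 10 to 14 and 5 to 10 (NM-401). The acute phase list of NM-401 on day 28 ranged from −0.259 (without NM-401 vehicle day 28 replicate 4) to 0.137 (without NM-401 vehicle day 28 replicate 3), where its sign turned and it was called (adjusted p 0.0217), and its lists became 10 without vehicle replicate 4. Arrays that moved a count by over 1.5 times were, for NRCWE-26 day 28, its replicate 2 (454) and vehicle replicate 2 (497), and for NM-401 day 28 its replicate 5 (1). Between particles on day 1 they were NM-401 replicate 1 (233), NM-401 vehicle replicates 2 (210), 3 (234) and 4 (552) and NRCWE-26 vehicle replicate 5 (236). On day 3 they were NM-401 replicates 1 (36) and 4 (40), NRCWE-26 replicates 1 (278), 2 (37), 3 (52) and 5 (51), NRCWE-26 vehicle replicates 1 (53) and 5 (66), and NM-401 vehicle replicates 1 (47), 3 (269), 4 (49) and 5 (49). On day 28 they were NRCWE-26 replicate 2 (165), its vehicle replicate 2 (172) and NM-401 vehicle replicate 4 (188). Between vehicle groups on day 1 they were NRCWE-26 replicates 1 (278) and 2 (233) and NM-401 replicates 1 (234), 2 (133), 3 (156) and 4 (772). On day 3 they were NRCWE-26 replicates 1 (54), 2 (75), 3 (70) and 5 (44) and NM-401 replicates 1 (21), 2 (306), 3 (439), 4 (29) and 5 (19), and on day 28 NM-401 replicate 3 (480).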

Other observations

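All comparisons in this part were chosen after the values were seen. Between the vehicle groups 22 features (20 with a symbol) passed with the same sign on days 1, 3 and 28, and 4 of them were small nuclear or nucleolar RNA genes, a share that was not tested. The U1 RNA gene Rnu1b6 differed by −2.01, −1.91 and −1.76 (NM-401 vehicle minus NRCWE-26 vehicle), the minor spliceosome RNA Rnu12 by −1.61, −1.42 and −1.34, the nucleolar RNA Rnu3b1 by −1.49, −1.74 and −1.39 and Snora47 by −1.57, −1.30 and −1.13. The clock-driven genes Tef (−1.27, −1.32 and −1.42) and Wee1 (−1.41, −1.41 and −1.05) were lower and the membrane protein gene Vapb (1.27, 1.102 and 1.18) and the choline kinase gene Chka (0.81, 1.05 and 0.75) higher. Across genes the vehicle differences of 2 days correlated with r of 0.481 (days 1 and 3), 0.369 (days 1 and 28) and 0.369 (days 3 and 28), and with 0.256, 0.197 and 0.236 after the clock covariates. Pairs of days shared 61, 60 and 36 genes of the same sign, against 1.19, 5.72 and 2.22 for independent lists.

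On day 28 the 4 groups were also set against each other. NM-401 exposed mice differed from NRCWE-26 exposed mice in 0 genes by limma (1010 unadjusted), and the NM-401 vehicle group from NRCWE-26 exposed mice in 0 (889 unadjusted). The NRCWE-26 vehicle group differed from each of the other 3 groups, in 759, 449 and 775 genes. In exposed mice the mean of Dbp lay between the vehicle group means on days 1 and 3. It was 0.22 ± 1.07 and −0.30 ± 0.70 (SD, n = 5) after NRCWE-26 and 0.33 ± 0.85 and 0.31 ± 0.99 after NM-401. The NM-401 vehicle means averaged the separate clusters given above, so no array lay at those means. Nr1d1, a repressor of the clock, was 1.87 ± 0.43 and 1.80 ± 0.43 in the vehicle groups of day 1 (NRCWE-26 and NM-401) and 0.32 ± 0.23 and 0.21 ± 0.18 in the exposed groups. Of the genes with a Cy5 change of 2 or more, the reference channel moved in the same direction in 70 of 86, 118 of 142 and 8 of 12 after NRCWE-26 and 84 of 95, 87 of 108 and 1 of 1 after NM-401.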
